A study of Escherichia coli BW25113 with 8 samples.

How the data were processed

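Messenger RNA was sequenced on an Illumina HiSeq instrument in Escherichia coli BW25113 and in a mutant lacking elongation factor 4 (EF4, gene lepA), each without and with tetracycline, with 2 replicates per group and 8 libraries in all. Drug dose, time of treatment and growth medium are not given in the sources used here. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.9; the genome build, annotation and counting method are not given in the sources used here, so no coordinates are reported. The deposited table holds RPKM (reads per kilobase of gene, scaled by library size) for 4760 genes with a product name for each and no gene symbols.

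The RPKM values were multiples of a common step within each library and gene, which allowed the total behind each library and the coding length behind each gene to be recovered: 14028049, 19611265, 14986069, 17226680, 15181804, 15642510, 10674654 and 12704195 reads for untreated wild type replicates 1 and 2, untreated mutant 1 and 2, treated wild type 1 and 2, and treated mutant 1 and 2. Whole read numbers, within a tolerance of 1e-05, were recovered at all 4713 genes with reads in some library, and 98.3% of the lengths were multiples of 3. Genes listed at 0 numbered from 91 to 623 per library, and 3 reads per kilobase corresponded to 0.153 to 0.281 RPKM. The table held 0 ribosomal or transfer RNA entries.

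Gene symbols were given to 1443 of 4760 entries by matching product name and coding length to the MG1655 annotation (assembly ASM584v2), where the pair pointed to 1 gene; 6 of these rest on the product name alone. Other entries keep the table's own identifier. The ompF and ompC entries share the product name phosphoporin PhoE and the acrA entry is named as MexE family, and these were told apart by length. The pairs gadA and gadB, and tufA and tufB, are near-identical, so reads may have been shared between them. Gene lists were written before the data were examined and hold 828 entries in 38 lists, of which 762 were identified (730 of 795 distinct genes). One list of genes disrupted in BW25113 had 25% identified and was not tested as a list, leaving 37.

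Values were analysed as log2(RPKM + 1), without further scaling, for the 4597 genes at 1 RPKM or more in at least 2 libraries. All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend and robust), leaving 4 residual degrees of freedom. The contrasts were tetracycline against none in each strain, mutant against wild type without and with tetracycline, and the interaction. P-values were adjusted by Benjamini and Hochberg within each contrast, and genes under 0.05 were called. Lists were tested with camera at its preset correlation of 0.01, adjusted over 185 tests (37 lists in 5 contrasts), again with an estimated correlation, and with fry. A count adjusted over the list alone uses the same p-values adjusted among the list's genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

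Genes named in the text were chosen by a rule set before the data were examined. Among genes called, with groups that did not overlap (not asked of the interaction) and a mean of 10 RPKM or more, these were the 10 largest rises and 10 largest falls per contrast. From each list with a camera call or at least 3 genes called, the 4 genes with the smallest p-values were added. Named whatever their result were lepA, lepB, rnc, era, lacZ, marA, marR, acrA, acrB, tolC, ompF, rmf, cspA, recA, katG, soxS and rpoS. The text gives a selection of these, and genes outside the rule are marked as chosen after their values were seen.

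Replicates correlated across genes at r = 0.918 in untreated wild type, 0.946 in untreated mutant, 0.959 in treated wild type and 0.916 in treated mutant (log2 values). Principal components 1 to 3 held 45.05%, 21.2% and 13.8% of the variance, the last parting replicates 1 and 2 in each group. The test was tried on simulated data with 200 changed genes: genes changed by 2, 4 and 16 fold were recovered at 1 of 67, 21 of 67 and 65 of 66 in the wild-type tetracycline contrast, and at 0 of 67, 2 of 67 and 37 of 66 in the interaction, while unchanged genes made up 3.33% to 7.14% of the calls over the 5 contrasts. Camera called a raised list in each contrast and 0 of 30 random lists. The simulated genes varied independently of each other, with 1 dispersion of 0.193 for all. The recovery applies to that setting, and the random lists could not test the preset correlation for genes regulated together.

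Alternatives were other pseudocounts (0.1 and 5), no filter and a stricter filter, eBayes without trend and robust, only the groups compared, a replicate block, and each library left out in turn. Quantile normalization was planned for single genes. Median centring, limma-voom on the recovered reads, and the list tests after quantile normalization or median centring were added after the data were seen. Choices that need read counts as deposited were not applied, since the table holds RPKM.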

Results

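The series compared Escherichia coli BW25113 (WT) with a mutant lacking elongation factor 4 (ΔEF4), a ribosome-binding GTPase encoded by lepA. Each strain was sampled without and with tetracycline (WT+tet, ΔEF4+tet), an antibiotic that blocks tRNA entry to the ribosome. In the wild type, 19 of 54 ribosomal protein, 8 of 22 heat shock and 3 of 7 isc operon genes rose with tetracycline. With it 12 of 13 acid resistance, 18 of 29 anaerobic respiration and 13 of 23 general stress genes fell. Without WT+tet replicate 2 these counts were 0, 2, 2, 7, 6 and 4, in that order, and without WT replicate 2 0, 3, 0, 10, 10 and 8. After quantile normalization 3 ribosomal protein genes rose. In the mutant, 4 of 13 acid resistance genes and 9 of 23 general stress genes rose instead, although 2 acid resistance genes fell. Without ΔEF4 replicate 2 limma called 0 of these rises, with 9 and 11 at an unadjusted p under 0.05. Without ΔEF4+tet replicate 2 it also called 0, with 9 and 15. In the mutant 32 of 52 flagellar and chemotaxis genes fell (6 to 29 without 1 library), and 6 of 18 aromatic amino acid genes rose. With the drug, 50 of 54 ribosomal protein genes lay lower in the mutant than in the wild type, and 12 of 13 acid resistance genes lay higher. None of the calls of gene lists given below was kept with an estimated correlation (adjusted p = 0.439 or more). Each group held 2 libraries. Values after a gene are log2 fold changes of RPKM plus 1 ± SE from limma, a scale that understates changes of genes near 0. Genes said to rise or fall had an adjusted p under 0.05. Growth stage at harvest is not given and stays open as a cause of changes with tetracycline. Ranges marked as without 1 library cover each of the 8 left out in turn. The p-values measure the spread between these libraries, since the labels do not say whether replicates were separate cultures.

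The elongation factor 4 gene itself, lepA, was at 384 and 335 RPKM in WT and 386 and 394 RPKM in WT+tet. In the mutant it was at 3.45 and 8.16 RPKM without and 11.03 and 14.8 RPKM with the drug. It fell in the mutant without the drug (-5.82 ± 0.46, adjusted p = 0.00506), a call lost without WT replicate 2 (adjusted p = 0.0852), and with it (-4.83 ± 0.46, adjusted p = 0.00084). Tetracycline did not move it past the threshold in the wild type (0.12 ± 0.46, adjusted p = 0.9) or in the mutant (1.11 ± 0.46, adjusted p = 0.19). The signal peptidase gene lepB, which is transcribed with lepA, did not pass in the mutant without (0.53 ± 0.36, adjusted p = 0.516) or with the drug (1.08 ± 0.36, adjusted p = 0.0804). Further along the same strand, the ribonuclease gene rnc was at -1.26 ± 0.50, adjusted p = 0.284 without and -0.91 ± 0.50, adjusted p = 0.257 with the drug. The ribosome assembly GTPase gene era was at -1.09 ± 0.40, adjusted p = 0.25 and -1.13 ± 0.40, adjusted p = 0.0892. Upstream, rseA (2.02 ± 0.40), which codes for the anti-sigma factor of the envelope stress sigma factor, rose in the mutant with the drug, as did rseB (1.88 ± 0.54) and rseC (1.64 ± 0.41). Those 3 calls were each lost without a WT+tet library, at adjusted p up to 0.0774, 0.279 and 0.189. Neighbours were read from the MG1655 annotation, assembly ASM584v2.

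**Figure D1:**
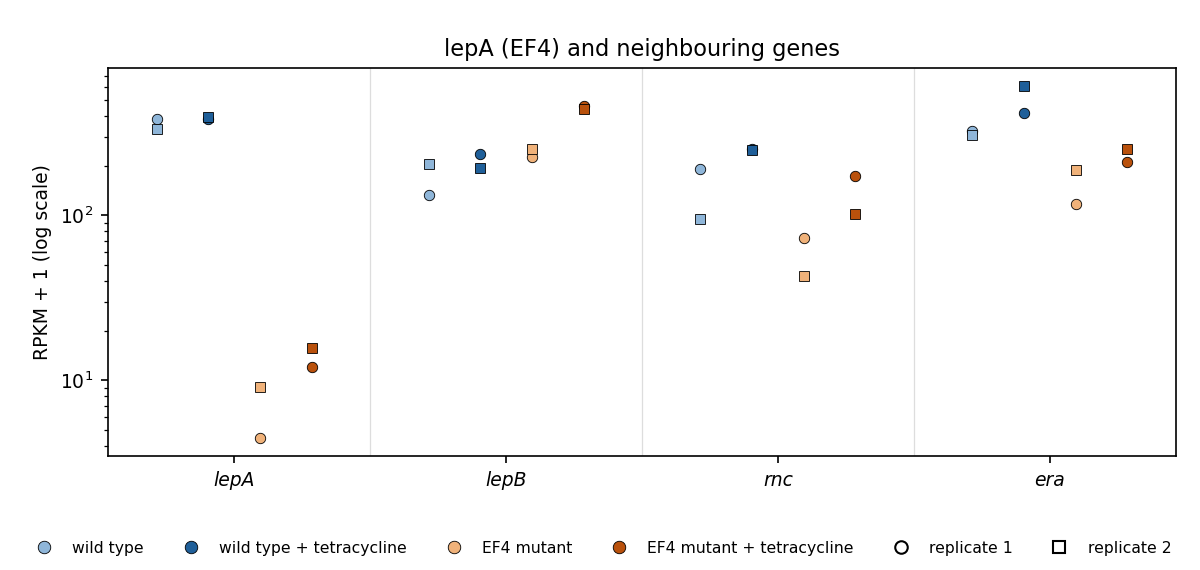
RPKM plus 1 of lepA and its neighbours in each of the 8 libraries on a log scale, circles for replicate 1 and squares for replicate 2.

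Genes of acid resistance fell in the wild type with tetracycline. The largest fall was that of hdeB (-9.69 ± 0.60), which with hdeA (-8.72 ± 0.52) codes for periplasmic chaperones that protect proteins at low pH. Of these, hdeA went from 13164 ± 8448 to 26.9 ± 4.43 RPKM (mean ± SD). Also lower were gadE (-7.41 ± 0.60), the activator of the glutamate-dependent acid response, and slp (-7.33 ± 0.72), a lipoprotein gene of the same region. The decarboxylase genes gadB (-7.14 ± 1.03) and cadA (-7.29 ± 0.42) fell as well; gadB is hard to tell from its near-identical paralog gadA. Of 13 acid resistance genes, 0 rose and 12 fell (0 and 13 adjusted over the list alone; 0 and 7 to 13 without 1 library). Acid resistance genes had a median of -6.51, -6.53 relative to all genes, with camera adjusted p = 4.70e-14 and adjusted p = 0.446 with an estimated correlation. That list had 13 of its 19 genes identified. Anaerobic genes that fell included dmsA (-4.94 ± 0.43) for dimethyl sulfoxide reductase, nikA (-4.64 ± 0.50) for nickel uptake and hybA (-4.53 ± 0.51) and hybO (-4.53 ± 0.54) for a hydrogenase. Of 29 anaerobic respiration genes, 0 rose and 18 fell (0 and 21 adjusted over the list alone; 0 and 6 to 22 without 1 library). Anaerobic respiration genes had a median of -3.53, -3.56 relative to all genes, with camera adjusted p = 3.92e-14 and adjusted p = 0.457 with an estimated correlation. General stress genes that depend on sigma S fell too, among them the catalase gene katE (-4.995 ± 0.39), the DNA-protecting dps (-4.39 ± 0.44), the lipoprotein gene osmE (-4.54 ± 0.40) and the transketolase gene tktB (-3.85 ± 0.43). Of 23 general stress genes, 0 rose and 13 fell (0 and 15 adjusted over the list alone; 0 and 4 to 11 without 1 library). General stress genes had a median of -2.54, -2.57 relative to all genes, with camera adjusted p = 8.56e-09 and adjusted p = 0.439 with an estimated correlation. The sigma S gene rpoS itself did not pass (-0.03 ± 0.35, adjusted p = 0.971). The peroxide response overlaps general stress in katE and dps, and its peroxidase gene katG (-3.30 ± 0.55) fell. Of 19 peroxide response genes, 0 rose and 8 fell (2 and 11 adjusted over the list alone; 0 to 1 and 2 to 7 without 1 library). Peroxide response genes had a median of -1.48, -1.503 relative to all genes, with camera adjusted p = 0.000227 and adjusted p = 0.439 with an estimated correlation.

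Ribosomal protein genes rose in the wild type with tetracycline, the smallest p-values being those of rpmB (2.56 ± 0.40), rplT (2.10 ± 0.36), rpmC (2.19 ± 0.40) and rpsK (2.01 ± 0.38). Of these, rpmC went from 3351 ± 1052 to 14934 ± 336 RPKM. Of 54 ribosomal protein genes, 19 rose and 0 fell (43 and 0 adjusted over the list alone; 0 to 22 and 0 without 1 library; rises numbered 8 in eBayes without trend and robust and 3 after quantile normalization). Ribosomal protein genes had a median of 1.69, 1.67 relative to all genes, with camera adjusted p = 7.69e-17 and adjusted p = 0.439 with an estimated correlation. Quantile normalization gave them a median of 0.86 and adjusted p = 0.0007. The RNA helicase gene deaD, which acts in ribosome assembly and at low temperature, rose from 86.7 ± 17.4 to 2696 ± 419 RPKM (4.95 ± 0.38, adjusted p = 0.000483). The assembly factor genes rimM (2.33 ± 0.54) and rhlE (2.07 ± 0.45) rose as well. Of 16 ribosome assembly factor genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; 1 to 3 and 0 without 1 library). Ribosome assembly factor genes had a median of 0.63, 0.60 relative to all genes, with camera adjusted p = 0.00769 and adjusted p = 0.439 with an estimated correlation. Quantile normalization gave them a median of 0.96 and adjusted p = 0.000968. That list had 78.3% of its genes identified. Among translation factors, the initiation factor gene infC (1.81 ± 0.37) rose. Of 16 translation factor genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; 0 to 1 and 0 without 1 library). Translation factor genes had a median of 0.61, 0.59 relative to all genes, with camera adjusted p = 0.0314 and adjusted p = 0.699 with an estimated correlation. The translation factor genes lost this call at adjusted p = 0.117 without WT replicate 2 and 0.181 without WT+tet replicate 2, and 0.0784 after quantile normalization. Heat shock genes rose, led by the small chaperone genes ibpB (5.53 ± 0.55) and ibpA (4.44 ± 0.35), with htpG (2.09 ± 0.38) and hslO (2.27 ± 0.42) behind them. Of 22 heat shock genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone; 2 to 10 and 0 without 1 library). Heat shock genes had a median of 1.55, 1.52 relative to all genes, with camera adjusted p = 7.15e-08 and adjusted p = 0.439 with an estimated correlation. The iron-sulfur cluster assembly genes iscR (3.09 ± 0.54), hscB (2.46 ± 0.40) and hscA (1.78 ± 0.38) of the isc operon rose. Of 7 isc operon genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone; 0 to 3 and 0 without 1 library). Isc operon genes had a median of 2.47, 2.44 relative to all genes, with camera adjusted p = 0.00026 and adjusted p = 0.547 with an estimated correlation. The largest rises were those of nrdH (6.12 ± 0.55) and nrdI (6.02 ± 0.59), which serve a ribonucleotide reductase used when iron is scarce. Their levels went from 0.724 ± 1.02 to 108 ± 11.3 RPKM and from 1.19 ± 0.279 to 141 ± 11.8 RPKM.

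Sugar uptake and glycolysis genes fell in the wild type with tetracycline. Maltose genes went furthest: the binding protein gene malE (-8.77 ± 0.66), the transport ATPase gene malK (-7.07 ± 0.48) and the maltoporin gene lamB (-6.93 ± 0.41). The trehalose hydrolase gene treC (-6.24 ± 0.54) followed. Of 55 carbohydrate uptake genes, 2 rose and 16 fell (4 and 18 adjusted over the list alone; 0 to 3 and 7 to 17 without 1 library). Carbohydrate uptake genes had a median of -1.26, -1.28 relative to all genes, with camera adjusted p = 6.18e-05 and adjusted p = 0.699 with an estimated correlation. Tryptophanase, tnaA, fell from 31312 ± 10398 to 182 ± 222 RPKM (-8.32 ± 1.15, adjusted p = 0.00596). The glycolysis genes pgi (-3.24 ± 0.35), fbaA (-3.24 ± 0.65) and pgk (-2.40 ± 0.44) fell. Of 18 glycolysis genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone; 0 and 1 to 8 without 1 library; falls numbered 5 with only the groups compared). Glycolysis genes had a median of -1.64, -1.67 relative to all genes, with camera adjusted p = 2.63e-05 and adjusted p = 0.439 with an estimated correlation. Of the outer membrane porins, ompC (-4.71 ± 0.39) fell while ompF (1.48 ± 0.34) and ompX (1.79 ± 0.46) rose, and the porin list gave no call (camera adjusted p = 0.658). The ompC and ompF entries carry the product name phosphoporin PhoE in the table and were told apart by coding length. Flagellar genes such as flgC (-4.75 ± 0.80) and fliO (-3.55 ± 0.62) fell. Of 52 flagellar and chemotaxis genes, 0 rose and 6 fell (0 and 6 adjusted over the list alone; 0 and 0 to 12 without 1 library; falls numbered 3 with limma-voom). Flagellar and chemotaxis genes had a median of -1.104, -1.13 relative to all genes, with camera adjusted p = 0.00169 and adjusted p = 0.76 with an estimated correlation. The flagellar and chemotaxis genes lost this call at adjusted p = 0.141 without WT replicate 1.

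Smaller list calls in the wild type with tetracycline concerned the envelope, nucleotides, toxins, iron and hibernation. The envelope stress chaperone gene cpxP (-2.11 ± 0.40) fell. Of 19 envelope stress genes, 0 rose and 2 fell (0 and 6 adjusted over the list alone; 0 and 0 to 5 without 1 library). Envelope stress genes had a median of -0.95, -0.98 relative to all genes, with camera adjusted p = 0.00345 and adjusted p = 0.53 with an estimated correlation. That list had 70.4% of its genes identified. The carbamoyltransferase gene pyrB (-4.18 ± 0.63) of pyrimidine synthesis fell. Of 24 purine and pyrimidine genes, 0 rose and 2 fell (0 and 8 adjusted over the list alone; 0 and 0 to 3 without 1 library). Purine and pyrimidine genes had a median of -0.75, -0.77 relative to all genes, with camera adjusted p = 0.00699 and adjusted p = 0.76 with an estimated correlation. The purine and pyrimidine genes lost this call at adjusted p = 0.111 without WT replicate 1. The toxin gene relE (2.33 ± 0.46) and the antitoxin gene prlF (2.02 ± 0.38) rose, on a list with 73.1% of its genes identified. Of 19 toxin-antitoxin genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone; 0 to 3 and 0 without 1 library). Toxin-antitoxin genes had a median of 0.51, 0.48 relative to all genes, with camera adjusted p = 0.0126 and adjusted p = 0.632 with an estimated correlation. The toxin-antitoxin genes lost this call at adjusted p = 0.0911 without WT replicate 2. The ferric reductase gene fhuF (2.59 ± 0.56) rose. Of 34 iron acquisition genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone; 0 to 1 and 0 without 1 library). Iron acquisition genes had a median of 0.54, 0.51 relative to all genes, with camera adjusted p = 0.0347 and adjusted p = 0.632 with an estimated correlation. The iron acquisition genes lost this call at adjusted p = 0.171 without WT replicate 2 and 0.142 without WT+tet replicate 2, and 0.1 after quantile normalization. The stationary-phase ribosome-associated gene sra (-3.89 ± 0.76) fell. Of 5 ribosome hibernation genes, 0 rose and 1 fell (0 and 2 adjusted over the list alone; 0 and 0 to 2 without 1 library). Ribosome hibernation genes had a median of -1.28, -1.31 relative to all genes, with camera adjusted p = 0.0493 and adjusted p = 0.457 with an estimated correlation. The ribosome hibernation genes lost this call at adjusted p = 0.126 without WT replicate 1 and 0.0628 without WT replicate 2, and 0.0851 after quantile normalization.

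Counted over all genes, 511 of 4597 passed in limma for tetracycline in the wild type, 174 higher and 337 lower, and the groups did not overlap at 58.3% of the 4597 genes tested, against 33.3% by chance. The count was 173 without WT replicate 2, 194 without WT+tet replicate 1 and 100 without WT+tet replicate 2. A group left with 1 library was assumed to vary like the others. Of the 69 genes past the threshold that the rule named, 30 passed without each of the 8 libraries in turn and 39 did not, their highest adjusted p being 0.285. Of the genes given above for this comparison, those that passed without each library were hdeB, hdeA, gadE, slp, cadA, dmsA, nikA, hybA, hybO, katE, dps, osmE, tktB, deaD, ibpB, ibpA, nrdH, nrdI, malE, malK, lamB, treC, tnaA, pgi and ompC.

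In the mutant with tetracycline, genes of flagella fell and those of tryptophan supply rose. Rod and hook genes fell most, flgB (-9.28 ± 0.83), flgC (-8.50 ± 0.80) and flgD (-8.03 ± 0.75), with the export gene fliO (-6.99 ± 0.62) close to them. Of these, flgB went from 2641 ± 725 to 4.15 ± 4.28 RPKM. Of 52 flagellar and chemotaxis genes, 0 rose and 32 fell (0 and 43 adjusted over the list alone; 0 and 6 to 29 without 1 library). Flagellar and chemotaxis genes had a median of -3.70, -4.20 relative to all genes, with camera adjusted p = 5.55e-54 and adjusted p = 0.439 with an estimated correlation. Between the treated strains, 3 of these genes lay higher in the mutant and 0 lower, with a median of 0.56. Camera gave no call there (adjusted p = 0.0786), but called them higher after quantile normalization (adjusted p = 0.00686). The threonine degradation genes tdcE (-7.90 ± 0.47) and tdcF (-7.56 ± 0.38) fell, tdcE from 5049 ± 664 to 22.1 ± 13.6 RPKM. Maltose uptake fell here as in the wild type, with malK (-7.41 ± 0.48), lamB (-7.26 ± 0.41) and malE (-6.55 ± 0.66). Of 55 carbohydrate uptake genes, 0 rose and 8 fell (0 and 9 adjusted over the list alone; 0 and 4 to 8 without 1 library). Carbohydrate uptake genes had a median of -0.85, -1.35 relative to all genes, with camera adjusted p = 5.02e-14 and adjusted p = 0.525 with an estimated correlation. The tryptophan permease gene mtr rose from 11.9 ± 2.62 to 937 ± 211 RPKM (6.18 ± 0.43, adjusted p = 0.000529), and the synthesis genes trpE (5.68 ± 0.68), trpD (5.04 ± 0.62) and aroH (3.75 ± 0.39) rose with it. Of 18 aromatic amino acid genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone). Aromatic amino acid genes had a median of 1.36, 0.86 relative to all genes, with camera adjusted p = 0.000242 and adjusted p = 0.439 with an estimated correlation. In the wild type mtr was at -0.12 ± 0.43, adjusted p = 0.886 with the drug, and trpE at 0.11 ± 0.68, adjusted p = 0.939.

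Acid resistance genes parted in the mutant with tetracycline. The decarboxylase gene gadA (5.12 ± 0.85), the antiporter gene gadC (5.05 ± 0.87) and the activator gadE (3.87 ± 0.60) rose, while the lysine decarboxylase gene cadA (-4.67 ± 0.42) fell as in the wild type. Of 13 acid resistance genes, 4 rose and 2 fell (10 and 2 adjusted over the list alone; 0 to 10 and 1 to 2 without 1 library). Acid resistance genes had a median of 2.91, 2.41 relative to all genes, with camera adjusted p = 0.0493 and adjusted p = 0.823 with an estimated correlation. They lost this call without ΔEF4 replicate 1, either WT+tet replicate or ΔEF4+tet replicate 2, and with a replicate block (adjusted p = 0.0522). General stress genes rose, among them the alkylation response gene aidB (3.50 ± 0.44), the trehalose synthesis gene otsA (2.87 ± 0.46) and tktB (2.67 ± 0.43) and yjbJ (3.81 ± 0.64). Of 23 general stress genes, 9 rose and 0 fell (16 and 0 adjusted over the list alone; 0 to 8 and 0 without 1 library; rises numbered 5 with only the groups compared and 5 after median centring). General stress genes had a median of 2.16, 1.66 relative to all genes, with camera adjusted p = 1.90e-06 and adjusted p = 0.473 with an estimated correlation. The iron-sulfur assembly genes sufB (2.98 ± 0.47), sufD (2.61 ± 0.46) and sufS (2.91 ± 0.54) of the peroxide response rose. Of 19 peroxide response genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; 0 to 4 and 0 without 1 library; rises numbered 1 with only the groups compared). This list gave no call (camera adjusted p = 0.106). The glyoxylate shunt genes aceA (4.75 ± 0.58), aceK (5.10 ± 0.68) and aceB (3.86 ± 0.64) rose. Their list, the TCA cycle, had a median of -0.92, a mean of 0.06 and no call (camera adjusted p = 0.105, direction down). A replicate block called it lower (adjusted p = 0.0306).

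Ribosomal protein genes lay lower in the mutant with tetracycline than without, with rpsQ (-1.89 ± 0.37) and rplP (-1.82 ± 0.36) as examples. Of 54 ribosomal protein genes, 0 rose and 5 fell (0 and 8 adjusted over the list alone; 0 and 0 to 5 without 1 library; falls numbered 0 with only the groups compared, 0 in eBayes without trend and robust and 8 after median centring). Ribosomal protein genes had a median of -0.69, -1.19 relative to all genes, with camera adjusted p = 2.17e-12 and adjusted p = 0.439 with an estimated correlation. Quantile normalization gave them a median of -0.86, against 0.86 in the wild type. The ATP synthase gene atpC (-2.37 ± 0.47) fell. Of 9 ATP synthase genes, 0 rose and 1 fell (0 and 6 adjusted over the list alone; 0 and 0 to 1 without 1 library). ATP synthase genes had a median of -1.501, -1.98 after median centring, with camera adjusted p = 1.44e-06 and adjusted p = 0.439 with an estimated correlation. The porin gene ompF (-2.47 ± 0.34) fell, where it rose in the wild type. Of 11 porin genes, 0 rose and 2 fell (1 and 4 adjusted over the list alone; 0 and 1 to 2 without 1 library). Porin genes had a median of -1.24, -1.74 relative to all genes, with camera adjusted p = 8.04e-05 and adjusted p = 0.446 with an estimated correlation. Of 29 anaerobic respiration genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone; 0 to 2 and 0 to 2 without 1 library). Anaerobic respiration genes had a median of -0.73, -1.23 relative to all genes, with camera adjusted p = 2.07e-05 and adjusted p = 0.632 with an estimated correlation. Of 7 fatty acid degradation genes, 0 rose and 0 fell (0 and 3 adjusted over the list alone; 0 and 0 to 2 without 1 library). Fatty acid degradation genes had a median of -1.71, -2.21 relative to all genes, with camera adjusted p = 0.000204 and adjusted p = 0.56 with an estimated correlation. Of 23 aminoacyl-tRNA synthetase genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone). Aminoacyl-tRNA synthetase genes had a median of -0.20, -0.70 relative to all genes, with camera adjusted p = 0.0196 and adjusted p = 0.766 with an estimated correlation. They lost this call without replicate 2 of ΔEF4 or of ΔEF4+tet, and after quantile normalization (median -0.39, adjusted p = 0.113). The small chaperone gene ibpA (1.83 ± 0.35) and the heat shock gene hslJ (1.75 ± 0.34) rose. Of 22 heat shock genes, 2 rose and 0 fell (8 and 0 adjusted over the list alone; 0 to 2 and 0 without 1 library). Heat shock genes had a median of 1.104, 0.60 relative to all genes, with camera adjusted p = 0.000851 and adjusted p = 0.439 with an estimated correlation. The toxin gene yafO (2.44 ± 0.49) and the expression modulator gene hha (2.33 ± 0.47) rose. Of 19 toxin-antitoxin genes, 3 rose and 0 fell (8 and 0 adjusted over the list alone; 0 to 3 and 0 without 1 library). Toxin-antitoxin genes had a median of 1.21, 0.71 relative to all genes, with camera adjusted p = 0.00999 and adjusted p = 0.632 with an estimated correlation. The toxin-antitoxin genes lost this call at adjusted p = 0.117 without ΔEF4 replicate 2. The cold shock genes cspA (3.02 ± 0.61) and cspB (4.80 ± 0.91) rose.

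Counted over all genes, 221 passed in limma for tetracycline in the mutant, 141 higher and 80 lower, and the groups did not overlap at 54.2% of the 4597 genes tested, against 33.3% by chance. The median log2 fold change of all genes was 0.50, against 0.02 in the wild type, so list medians are also given relative to it, or after median centring for ATP synthase. After quantile normalization the split was 83 higher and 119 lower, and after median centring 72 and 137. The count was 75 (42 higher and 33 lower) without ΔEF4 replicate 1, 22 (4 higher and 18 lower) without ΔEF4 replicate 2, 121 (72 higher and 49 lower) without ΔEF4+tet replicate 1 and 53 (9 higher and 44 lower) without ΔEF4+tet replicate 2. It was 90 (44 higher and 46 lower) without WT+tet replicate 1 and 87 (41 higher and 46 lower) without WT+tet replicate 2, which enter through the shared error estimate. Of the 48 genes past the threshold that the rule named, 15 passed without each of the 8 libraries in turn and 33 did not, their highest adjusted p being 0.249. Of the genes given above for this comparison, those that passed without each library were flgB, flgC, flgD, fliO, tdcE, tdcF, malK, lamB, malE, mtr, trpE, trpD, aroH and cadA. Across genes, the tetracycline responses of the 2 strains had Pearson r = 0.138, where genes are not independent replicates. Genes that rose in both numbered 10, against 5.34 if the calls were independent, and genes that fell in both 32, against 5.86. Another 43 were called in opposite directions. Left out in the order WT, ΔEF4, WT+tet and ΔEF4+tet, replicate 1 before 2, the libraries gave 42, 21, 8, 0, 12, 11, 31 and 3 genes in opposite directions. In the same order, limma gave 7, 4, 2, 0, 2, 1, 6 and 0 genes that rose in both and 28, 33, 18, 17, 14, 11, 24 and 19 that fell in both.

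**Figure D2:**
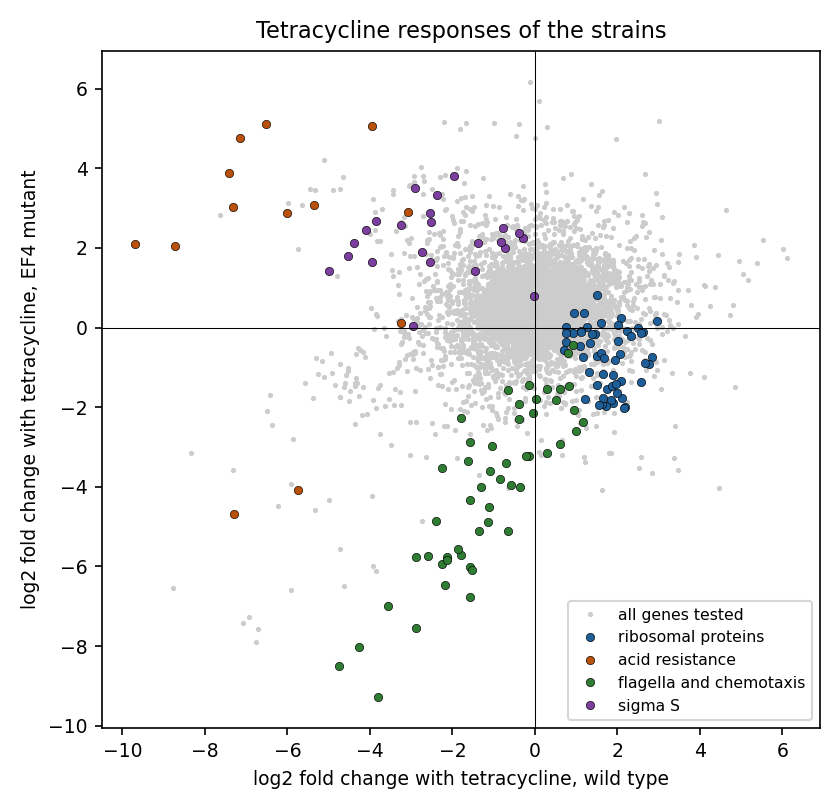
Log2 fold change with tetracycline in the wild type (x) and in the mutant (y) for each gene tested, with the lists named in the key in colour.

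Without the drug, the mutant differed from the wild type mainly in flagellar genes, which lay higher. Flagellin, fliC, was at 69.04 ± 5.45 RPKM in WT and 6786 ± 333 RPKM in ΔEF4 (6.60 ± 1.08, adjusted p = 0.0446). The hook gene flgD (5.22 ± 0.75), the rod gene flgB (5.17 ± 0.83), the filament cap gene fliD (5.49 ± 0.89) and the chemotaxis genes cheA (5.31 ± 0.85), cheW (5.29 ± 0.79) and cheZ (4.54 ± 0.59) rose with it. Of 52 flagellar and chemotaxis genes, 28 rose and 0 fell (48 and 0 adjusted over the list alone; 0 to 27 and 0 without 1 library; rises numbered 9 with only the groups compared and 0 with a pseudocount of 0.1). Flagellar and chemotaxis genes had a median of 4.12, 4.52 relative to all genes, with camera adjusted p = 3.53e-72 and adjusted p = 0.439 with an estimated correlation. At a pseudocount of 0.1, limma had 48 of the 52 higher at an unadjusted p under 0.05, with a median of 4.33. Also higher was pdeH (5.91 ± 0.98), which codes for a phosphodiesterase that lowers cyclic di-GMP and frees the flagellar motor. Outside motility, the alternative ribosomal protein gene ykgM (5.83 ± 0.53), used when zinc is scarce, and rclC (5.44 ± 0.59), induced by reactive chlorine, rose.

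**Figure D3:**
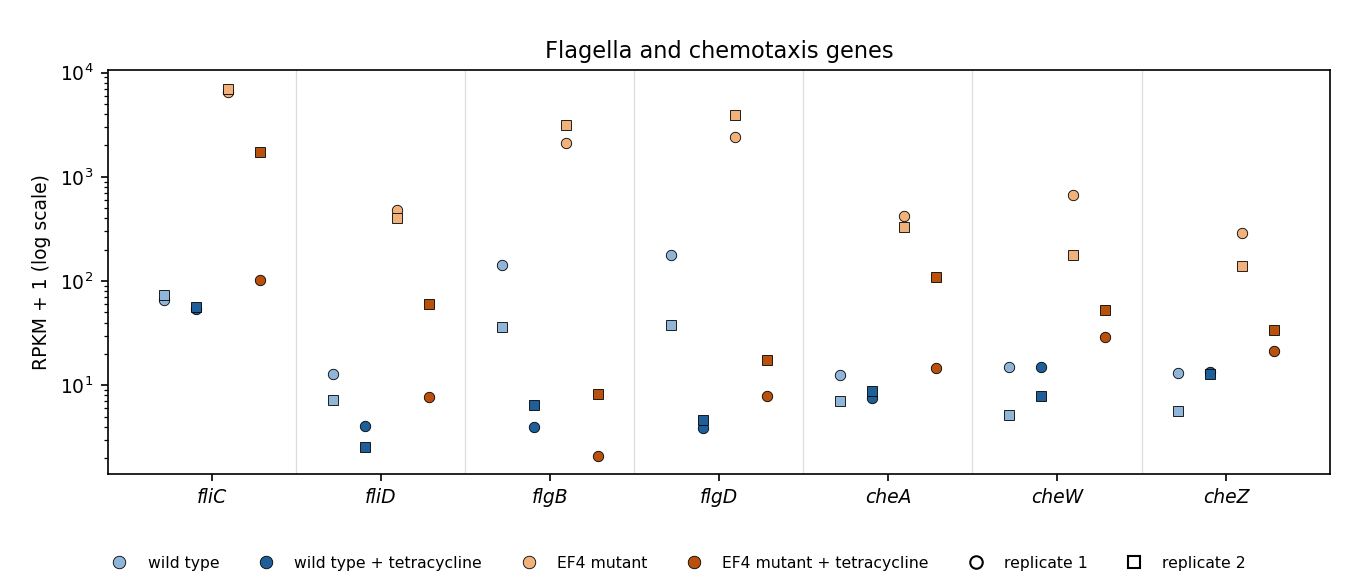
RPKM plus 1 of flagellar and chemotaxis genes in each of the 8 libraries on a log scale, circles for replicate 1 and squares for replicate 2.

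Among the genes that fell in the mutant without the drug, beside lepA, were the prophage lipoprotein gene borD (-6.10 ± 0.76) and gene619 (-4.14 ± 0.70), annotated as a murein endopeptidase of the same prophage. The formate dehydrogenase genes fdoH (-5.12 ± 0.42) and fdoI (-3.67 ± 0.50) of the fdo operon fell. They stood at 2.64% and 7.02% of their wild-type mean without, and 2.08% and 1.33% with the drug. The entry taken as fdoG, the alpha subunit gene of that operon, was picked by length from a pair with the same product name. It was at 27.9% without (-1.88 ± 0.45, adjusted p = 0.11) and 9.54% with the drug (-3.44 ± 0.45, adjusted p = 0.00223). The putrescine importer gene plaP stood at 13.3% without (-2.56 ± 0.48, adjusted p = 0.0513) and 6.35% with the drug (-3.72 ± 0.48, adjusted p = 0.00203). Both fdoG and plaP were chosen after their values were seen. The cold shock gene cspA fell from 2326 ± 1435 to 169 ± 0.335 RPKM (-3.62 ± 0.61, adjusted p = 0.0446). The exonuclease gene xseA (-2.57 ± 0.41) and the entericidin gene ecnA (-2.48 ± 0.40) fell too.

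**Figure D4:**
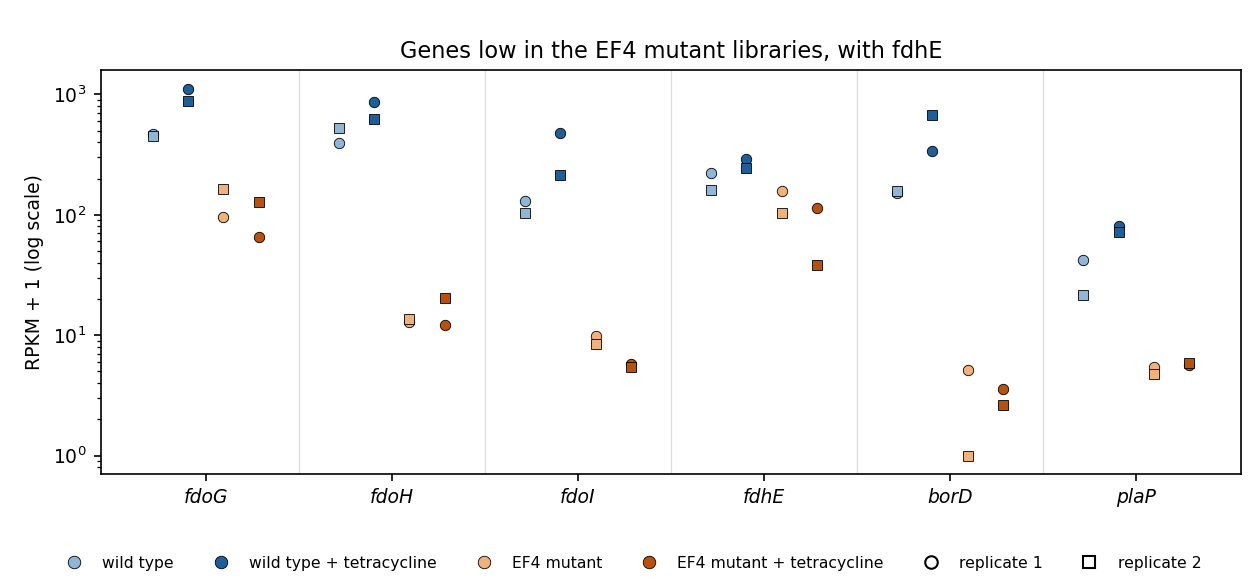
RPKM plus 1 of genes at a small share of their wild-type level in the mutant, and of neighbouring fdo genes, in each of the 8 libraries on a log scale, circles for replicate 1 and squares for replicate 2.

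Beside the flagellar list and the cold shock list, where cspA was the 1 gene of 18 called, no list held a gene past the threshold over all genes between the untreated strains. Higher in the mutant as lists were fatty acid degradation, heat shock, phage shock, carbohydrate uptake, anaerobic respiration, TCA cycle and porin genes. Fatty acid degradation genes had a median of 2.17, 2.57 relative to all genes, with camera adjusted p = 1.67e-06 and adjusted p = 0.472 with an estimated correlation. Heat shock genes had a median of 0.24, 0.64 relative to all genes, with camera adjusted p = 0.00175 and adjusted p = 0.439 with an estimated correlation. Phage shock genes had a median of 0.98, 1.38 relative to all genes, with camera adjusted p = 0.00648 and adjusted p = 0.494 with an estimated correlation. Carbohydrate uptake genes had a median of 0.57, 0.97 relative to all genes, with camera adjusted p = 2.68e-05 and adjusted p = 0.699 with an estimated correlation. The carbohydrate uptake genes lost this call at adjusted p = 0.0843 without WT replicate 1. Anaerobic respiration genes had a median of 0.42, 0.82 relative to all genes, with camera adjusted p = 0.00474 and adjusted p = 0.766 with an estimated correlation. The anaerobic respiration genes lost this call at adjusted p = 0.304 without WT replicate 1. TCA cycle genes had a median of 0.24, 0.64 relative to all genes, with camera adjusted p = 0.0235 and adjusted p = 0.779 with an estimated correlation. The TCA cycle genes lost this call at adjusted p = 0.954 without WT replicate 2 and 0.102 without ΔEF4 replicate 2, and 0.255 after quantile normalization and 0.0807 after median centring. Porin genes had a median of 0.29, 0.69 relative to all genes, with camera adjusted p = 0.0291 and adjusted p = 0.632 with an estimated correlation. The porin genes lost this call at adjusted p = 0.276 without WT replicate 2 and 0.0889 without ΔEF4 replicate 1, and 0.162 after quantile normalization. Without WT replicate 1 the direction of the anaerobic list turned down, as did that of the TCA cycle without WT replicate 2.

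Lower in the mutant without the drug, as lists, were genes for the synthesis of amino acids and nucleotides, for efflux and for iron uptake. Histidine and branched-chain amino acid genes had a median of -0.89, -0.49 relative to all genes, with camera adjusted p = 0.0108 and adjusted p = 0.699 with an estimated correlation. They lost this call without WT replicate 2. Multidrug efflux genes had a median of -0.87, -0.47 relative to all genes, with camera adjusted p = 0.0115 and adjusted p = 0.699 with an estimated correlation. They lost this call without WT replicate 2 or ΔEF4 replicate 1. Purine and pyrimidine genes had a median of -0.82, -0.42 relative to all genes, with camera adjusted p = 0.0172 and adjusted p = 0.779 with an estimated correlation. The purine and pyrimidine genes lost this call at adjusted p = 0.255 without WT replicate 1 and 0.131 without ΔEF4 replicate 1. Aromatic amino acid genes had a median of -0.76, -0.36 relative to all genes, with camera adjusted p = 0.036 and adjusted p = 0.632 with an estimated correlation. The aromatic amino acid genes lost this call at adjusted p = 0.0687 without WT replicate 1, 0.0735 without WT replicate 2 and 0.155 without ΔEF4 replicate 1. Iron acquisition genes had a median of -0.61, -0.21 relative to all genes, with camera adjusted p = 0.0371 and adjusted p = 0.632 with an estimated correlation. They lost this call without WT replicate 1, either ΔEF4 replicate or either ΔEF4+tet replicate. It was also lost after quantile normalization (median -0.14, adjusted p = 0.342) and median centring (adjusted p = 0.0615).

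Counted over all genes, 57 passed in limma between the untreated strains, 46 higher and 11 lower in the mutant, and the groups did not overlap at 47.1% of the 4597 genes tested, against 33.3% by chance. The median of all genes was -0.40. A pseudocount of 0.1 left 4 calls, 2 higher and 2 lower, with 722 genes at an unadjusted p under 0.05, and only the groups compared 24, 20 and 4. After median centring 86 genes were higher and 6 lower, and after quantile normalization 68 and 7. Without WT replicate 2 limma called 0 genes, with 545 at an unadjusted p under 0.05, and without WT replicate 1 34. It called 2 without ΔEF4 replicate 1, 1 without ΔEF4 replicate 2, 6 without WT+tet replicate 1 and 6 without WT+tet replicate 2. Of the 22 genes past the threshold that the rule named, 0 passed without each of the 8 libraries in turn and 22 did not, their highest adjusted p being 0.256.

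With tetracycline, the strains differed most in acid resistance, where the mutant was higher. The glutamate decarboxylase genes gadB (11.74 ± 1.03) and gadA (11.58 ± 0.85), near-identical in sequence, were at 1.16 ± 0.352 and 1.41 ± 0.0684 RPKM in WT+tet. In ΔEF4+tet they were at 7645 ± 2959.5 and 8084 ± 4695 RPKM. Their activator gadE (11.44 ± 0.60), the chaperone genes hdeB (11.64 ± 0.60) and hdeA (10.68 ± 0.52) and slp (10.37 ± 0.72) rose alike. Of 13 acid resistance genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone). Acid resistance genes had a median of 8.17, 8.14 relative to all genes, with camera adjusted p = 2.17e-12 and adjusted p = 0.457 with an estimated correlation. General stress genes rose, among them dps (6.64 ± 0.44), aidB (6.61 ± 0.44), osmE (6.28 ± 0.40) and katE (5.85 ± 0.39). Of 23 general stress genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone). General stress genes had a median of 4.65, 4.62 relative to all genes, with camera adjusted p = 4.94e-14 and adjusted p = 0.439 with an estimated correlation. The sigma S gene rpoS rose by less (1.26 ± 0.35, adjusted p = 0.0394), and lost its call whichever library was left out (adjusted p up to 0.185). The suf assembly genes sufB (5.03 ± 0.47) and sufD (4.32 ± 0.46) and the peroxidase gene katG (2.60 ± 0.55) rose. Of 19 peroxide response genes, 11 rose and 0 fell (12 and 1 adjusted over the list alone). Peroxide response genes had a median of 2.60, 2.58 relative to all genes, with camera adjusted p = 1.49e-05 and adjusted p = 0.439 with an estimated correlation. Anaerobic genes that rose included hyaA (9.96 ± 1.37), hyaB (9.64 ± 1.097) and hybA (3.94 ± 0.51) for hydrogenases, narG (6.55 ± 0.78) for nitrate reductase and dmsA (3.91 ± 0.43). Of 29 anaerobic respiration genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone; 8 to 20 and 0 without 1 library). Anaerobic respiration genes had a median of 2.95, 2.92 relative to all genes, with camera adjusted p = 9.53e-09 and adjusted p = 0.553 with an estimated correlation.

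**Figure D5:**
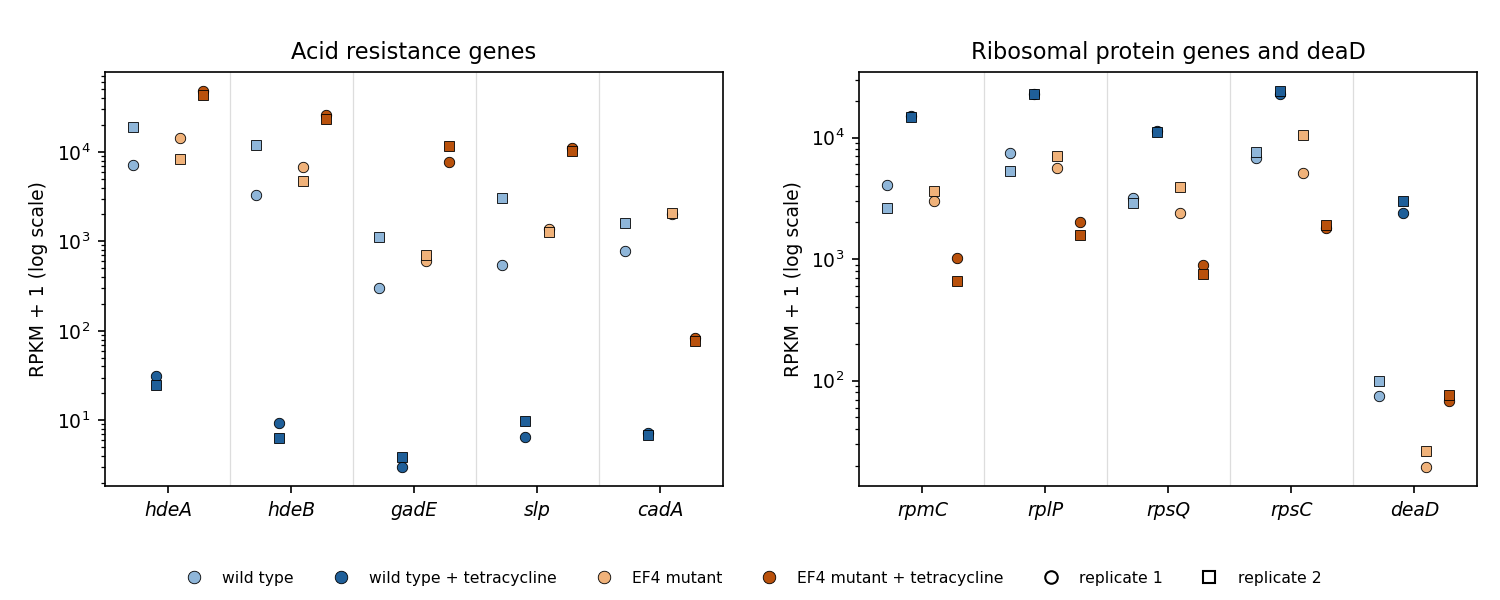
RPKM plus 1 of acid resistance genes, ribosomal protein genes and deaD in each of the 8 libraries on a log scale, circles for replicate 1 and squares for replicate 2.

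Ribosomal protein genes lay lower in the mutant with tetracycline, for instance rpmC (-4.18 ± 0.40), rpsQ (-3.76 ± 0.37), rplP (-3.67 ± 0.36) and rpsC (-3.66 ± 0.41). Of these, rplP was at 22726 ± 44.3 RPKM in WT+tet and 1799 ± 331 RPKM in ΔEF4+tet. Of 54 ribosomal protein genes, 0 rose and 50 fell (0 and 54 adjusted over the list alone; 0 and 30 to 49 without 1 library). Ribosomal protein genes had a median of -3.12, -3.14 relative to all genes, with camera adjusted p = 8.61e-28 and adjusted p = 0.439 with an estimated correlation. The elongation factor genes fusA (-2.20 ± 0.36), tsf (-3.60 ± 0.76) and tufB (-2.44 ± 0.45) fell, tufB being hard to tell from its paralog tufA. Of 16 translation factor genes, 0 rose and 7 fell (0 and 10 adjusted over the list alone; 0 and 0 to 8 without 1 library). Translation factor genes had a median of -1.61, -1.64 relative to all genes, with camera adjusted p = 6.67e-05 and adjusted p = 0.517 with an estimated correlation. The assembly genes deaD (-5.22 ± 0.38) and rimM (-3.72 ± 0.54) fell. Of 16 ribosome assembly factor genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone; 0 to 1 and 2 to 5 without 1 library; falls numbered 8 after quantile normalization). Ribosome assembly factor genes had a median of -0.93, -0.96 relative to all genes, with camera adjusted p = 0.0252 and adjusted p = 0.446 with an estimated correlation. The ribosome assembly factor genes lost this call at adjusted p = 0.057 without WT+tet replicate 2. Quantile normalization gave these genes a median of -1.44 and adjusted p = 0.00663. Ribosome hibernation genes rose, with sra (6.88 ± 0.76), raiA (3.75 ± 0.74) and hpf (2.25 ± 0.52), while rmf, the ribosome dimerization factor gene, did not pass (3.05 ± 0.96, adjusted p = 0.064). Of 5 ribosome hibernation genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone; 1 to 4 and 0 without 1 library). Ribosome hibernation genes had a median of 3.05, 3.03 relative to all genes, with camera adjusted p = 0.013 and adjusted p = 0.439 with an estimated correlation. The iron-sulfur genes hscA (-2.57 ± 0.38), hscB (-2.40 ± 0.40) and iscR (-2.66 ± 0.54) fell. Of 7 isc operon genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone; 0 and 2 to 6 without 1 library; falls numbered 3 with only the groups compared). Isc operon genes had a median of -2.66, -2.68 relative to all genes, with camera adjusted p = 0.000185 and adjusted p = 0.54 with an estimated correlation.

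Further genes of the core machinery lay lower in the mutant with the drug, such as the RNA polymerase subunit gene rpoA (-3.06 ± 0.44) and the ATP synthase gene atpB (-1.76 ± 0.39). Of 14 transcription machinery genes, 1 rose and 3 fell (1 and 6 adjusted over the list alone; 0 to 1 and 1 to 3 without 1 library). Transcription machinery genes had a median of -0.73, -0.75 relative to all genes, with camera adjusted p = 0.0114 and adjusted p = 0.632 with an estimated correlation. The transcription machinery genes lost this call at adjusted p = 0.0759 without WT+tet replicate 2. Of 9 ATP synthase genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone; 0 and 0 to 3 without 1 library). ATP synthase genes had a median of -0.89, -0.92 relative to all genes, with camera adjusted p = 0.0131 and adjusted p = 0.632 with an estimated correlation. The ATP synthase genes lost this call at adjusted p = 0.0556 without ΔEF4+tet replicate 2. The acetolactate synthase genes ilvM (-5.25 ± 0.69) and ilvG (-3.79 ± 0.48) and the ferric reductase gene fhuF (-3.83 ± 0.56) fell. Of 34 iron acquisition genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone). Iron acquisition genes had a median of -0.62, -0.64 relative to all genes, with camera adjusted p = 0.0158 and adjusted p = 0.632 with an estimated correlation. The iron acquisition genes lost this call at adjusted p = 0.0583 without WT+tet replicate 2 and 0.131 without ΔEF4+tet replicate 1. The genes borD (-7.30 ± 0.76), fdoH (-5.53 ± 0.42) and fdoI (-5.84 ± 0.50) fell as they did without the drug, and so did the redox regulator gene soxS (-1.96 ± 0.49) and cspA (-2.75 ± 0.61).

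Metabolic genes higher in the mutant with the drug included fbaB (5.46 ± 0.67) and pgi (2.79 ± 0.35) of glycolysis and aceA (4.04 ± 0.58) and aceK (4.54 ± 0.68) of the glyoxylate shunt. Of 18 glycolysis genes, 11 rose and 0 fell (12 and 0 adjusted over the list alone; 2 to 11 and 0 without 1 library; rises numbered 3 with only the groups compared and 7 after quantile normalization). Glycolysis genes had a median of 1.498, 1.47 relative to all genes, with camera adjusted p = 0.000286 and adjusted p = 0.439 with an estimated correlation. The tryptophan genes mtr (5.68 ± 0.43), trpE (4.90 ± 0.68) and trpD (4.39 ± 0.62) rose. Of 18 aromatic amino acid genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone; 3 to 5 and 0 without 1 library). This list gave no call here (camera adjusted p = 0.154). The periplasmic chaperone genes cpxP (3.59 ± 0.40) and spy (3.43 ± 0.59) rose. Of 19 envelope stress genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone; 3 to 6 and 0 without 1 library; rises numbered 3 with only the groups compared and 3 after quantile normalization). Envelope stress genes had a median of 0.82, 0.80 relative to all genes, with camera adjusted p = 0.0166 and adjusted p = 0.619 with an estimated correlation. The envelope stress genes lost this call at adjusted p = 0.128 without ΔEF4+tet replicate 1. Quantile normalization gave these genes a median of 0.39 and adjusted p = 0.0415. The porins parted, ompF falling from 1906 ± 34.3 to 151 ± 16.97 RPKM (-3.65 ± 0.34, adjusted p = 0.00074). At the same time ompC rose from 974 ± 151 to 13114 ± 3505 RPKM (3.73 ± 0.39, adjusted p = 0.0011). The efflux pump gene mdtE (7.55 ± 0.78), which is regulated by GadE, rose.

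Counted over all genes, 868 passed in limma between the treated strains, 568 higher and 300 lower in the mutant, and the groups did not overlap at 61.1% of the 4597 genes tested, against 33.3% by chance. After quantile normalization the split was 490 and 449. The count was 464 without WT+tet replicate 1, 300 without WT+tet replicate 2 and 480 without ΔEF4+tet replicate 2. Of the 106 genes past the threshold that the rule named, 52 passed without each of the 8 libraries in turn and 54 did not, their highest adjusted p being 0.279. Of the genes given above for this comparison, those that failed without at least 1 library were rseA, rseB, rseC, rpoS, katG, fusA, tsf, tufB, raiA, hpf, iscR, atpB, soxS and cspA. Across genes, the effects of the mutation with and without the drug had Pearson r = 0.238. Genes higher in both numbered 7, against 5.68 if the calls were independent, and genes lower in both 8, against 0.718. Genes higher in both numbered 19 against 3.51 without ΔEF4+tet replicate 1, 18 against 10.5 after median centring and 12 against 7.25 after quantile normalization. Left out in the order WT, ΔEF4, WT+tet and ΔEF4+tet, replicate 1 before 2, the libraries gave, in limma, 5, 0, 0, 0, 0, 0, 19 and 4 genes higher in both and 5, 0, 2, 1, 2, 2, 5 and 5 lower in both. Few calls without the drug were left in most of these, so an overlap beyond chance of the genes higher in both was left open.

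The interaction asked where the response to tetracycline differed between the strains, a positive value meaning a higher response in the mutant. Acid resistance genes differed most, with hdeB (11.79 ± 0.85), gadE (11.28 ± 0.85) and slp (10.35 ± 1.02). Of 13 acid resistance genes, 11 had a higher and 0 a lower response (12 and 0 adjusted over the list alone; 7 to 12 and 0 without 1 library). Acid resistance genes had a median of 8.99, 8.53 relative to all genes, with camera adjusted p = 2.17e-12 and adjusted p = 0.457 with an estimated correlation. General stress genes came next, with tktB (6.52 ± 0.61), dps (6.50 ± 0.63) and katE (6.40 ± 0.56). Of 23 general stress genes, 15 had a higher and 0 a lower response (19 and 0 adjusted over the list alone; 6 to 13 and 0 without 1 library). General stress genes had a median of 5.16, 4.70 relative to all genes, with camera adjusted p = 1.34e-12 and adjusted p = 0.439 with an estimated correlation. Ribosomal protein genes went the other way, with rpmC (-4.19 ± 0.56) and rpsQ (-3.77 ± 0.52). Of 54 ribosomal protein genes, 0 had a higher and 22 a lower response (0 and 35 adjusted over the list alone; 0 and 0 to 15 without 1 library; lower responses numbered 10 in eBayes without trend and robust and 7 after quantile normalization). Ribosomal protein genes had a median of -2.62, -3.08 relative to all genes, with camera adjusted p = 1.79e-29 and adjusted p = 0.439 with an estimated correlation. Flagellar genes responded lower in the mutant, with flgB (-5.47 ± 1.17) and flgA (-3.77 ± 0.81). Of 52 flagellar and chemotaxis genes, 0 had a higher and 6 a lower response (0 and 28 adjusted over the list alone; 0 and 0 to 17 without 1 library; lower responses numbered 11 with the stricter filter, 3 with a pseudocount of 0.1, 25 with a pseudocount of 5, 11 after quantile normalization and 18 after median centring). Flagellar and chemotaxis genes had a median of -3.05, -3.51 relative to all genes, with camera adjusted p = 1.37e-25 and adjusted p = 0.439 with an estimated correlation. The untreated mutant libraries, where these genes were high, also enter the flagellar results for the untreated strains and for tetracycline in the mutant. These are therefore not separate results. The permease gene mtr (6.30 ± 0.61) had a higher and the porin gene ompF (-3.94 ± 0.48) a lower response in the mutant.

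Counted over all genes, 323 passed in limma for the interaction, 256 positive and 67 negative, with a median of all genes of 0.46. After quantile normalization the split was 171 and 103, and after median centring 158 and 107. The count was 119 without WT replicate 2, 100 without ΔEF4 replicate 1 and 32 without ΔEF4 replicate 2. It was 146 and 39 without WT+tet replicates 1 and 2, and 174 and 135 without ΔEF4+tet replicates 1 and 2. Of the 56 genes past the threshold that the rule named, 15 passed without each of the 8 libraries in turn and 41 did not, their highest adjusted p being 0.166. Of the genes given above for this comparison, those that failed without at least 1 library were rpmC, rpsQ, flgB and flgA.

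Several genes often followed in work on tetracycline did not pass in any comparison. The multidrug resistance activator gene marA was at 1.17 ± 0.46, adjusted p = 0.151 in the wild type and 1.08 ± 0.46, adjusted p = 0.196 in the mutant with tetracycline. Its repressor gene marR was at 1.42 ± 1.16, adjusted p = 0.48 and 0.40 ± 1.16, adjusted p = 0.864. The efflux pump gene acrA, whose entry is named as MexE family and was matched by length, was at -0.87 ± 0.61, adjusted p = 0.407 and 0.60 ± 0.61, adjusted p = 0.586. Its partner genes were at -0.22 ± 0.54, adjusted p = 0.841 and 0.20 ± 0.54, adjusted p = 0.855 for acrB, and -1.502 ± 0.42, adjusted p = 0.0589 and -0.35 ± 0.42, adjusted p = 0.646 for tolC. The DNA repair gene recA was at 0.23 ± 0.61, adjusted p = 0.853 and -0.34 ± 0.61, adjusted p = 0.764, and lacZ, disrupted in this strain, at 1.02 ± 0.63, adjusted p = 0.345 and 1.28 ± 0.63, adjusted p = 0.253. Small changes were not detectable with 2 libraries per group: on simulated data the test recovered 1 of 67 genes changed by 2 fold and 21 of 67 changed by 4 fold in the wild-type tetracycline comparison.

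Camera, with its preset correlation, called 73 of 185 list tests, and 44 of these were kept without each library. With an estimated correlation it called 0, with 18 at an unadjusted p under 0.05. A further test, fry, which asks whether the genes of a list move one way on balance, called 55 of the 185, and of the 73 camera calls 38 were kept by fry and 35 were not. The direction of each of the 73 was the same after quantile normalization and after median centring.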

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

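The interaction test flagged the results in this part, because the response to tetracycline differed between the strains: limma called 323 genes and camera 16 lists. Lists with a higher response in the mutant had median log2 interactions of 8.99 (acid resistance), 5.16 (general stress), 2.96 (anaerobic respiration), 2.51 (ribosome hibernation), 2.42 (peroxide response), 1.65 (glycolysis), 1.34 (aromatic amino acids) and 1.24 (envelope stress). Lists with a lower response had medians of -3.05 (flagella), -2.62 (ribosomal proteins), -2.31 (fatty acid degradation), -2.15 (isc genes), -0.77 (ATP synthase), -0.56 (translation factors), -0.40 (transcription machinery) and -0.33 (heat shock). Each of the 16 calls had an adjusted p of 0.439 or more with an estimated correlation. Those of ATP synthase, transcription machinery, envelope stress, heat shock, ribosome hibernation and aromatic amino acids were lost without at least 1 library (ATP synthase 0.0643 without WT replicate 1; transcription machinery 0.084 without WT replicate 1, 0.238 without ΔEF4 replicate 2, 0.203 without WT+tet replicate 2 and 0.0568 without ΔEF4+tet replicate 2; envelope stress 0.066 without WT replicate 2, 0.0888 without ΔEF4 replicate 1 and 0.126 without ΔEF4+tet replicate 1; heat shock 0.0734 without ΔEF4+tet replicate 1; ribosome hibernation 0.109 without WT replicate 1, 0.0616 without WT replicate 2 and 0.0734 without ΔEF4+tet replicate 1; aromatic amino acids 0.0592 without ΔEF4+tet replicate 1). After quantile normalization the calls of heat shock (adjusted p = 0.0547) and transcription machinery (adjusted p = 0.0671) were lost. The median interaction of all genes was 0.46. After quantile normalization the list medians were -0.91 (heat shock), -0.73 (transcription machinery), -0.98 (translation factors), -1.18 (ATP synthase) and 0.64 (aromatic amino acids).

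Single genes flagged by the same test as responding higher in the mutant were gadB (11.89 ± 1.46), hdeB (11.79 ± 0.85), gadA (11.62 ± 1.20), gadE (11.28 ± 0.85), hdeA (10.78 ± 0.74), slp (10.35 ± 1.02), gadC (8.99 ± 1.23), the hypothetical protein genes gene3865 (10.46 ± 0.84) and gene3858 (9.32 ± 0.85), and gene3860 (9.11 ± 0.86), annotated as a magnesium transporter ATPase. Responding lower were the lactate permease gene lldP (-8.51 ± 1.90), the galactoside transport gene mglA (-6.49 ± 1.33), the rod gene flgB (-5.47 ± 1.17), the motor ring gene fliF (-4.55 ± 1.03), the glycolate regulator gene glcC (-5.01 ± 0.93), the sialic acid lyase gene nanA (-4.60 ± 0.94) and the porin gene ompF (-3.94 ± 0.48). Also lower were gene1594 (-7.05 ± 1.1001), gene345 (-5.34 ± 0.80) and gene2399 (-4.58 ± 0.90), annotated as transcriptional regulators, and gene328 (-4.95 ± 1.19), annotated as a ribosomal protein and at most at 33.6 RPKM. All are log2 interactions ± SE, and among the genes responding lower only ompF kept its call without each library.

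Of the tests of the opposite responses of ribosomal protein and acid resistance genes, leaving out libraries was planned for list calls, and the other tests and the bounds were chosen after the result was seen. Scaling and a single library were excluded as the whole cause of the difference between strains. Either list's median interaction lay at least 1.77 from that of all genes after quantile normalization and 2.71 without 1 library, direction kept. Median centring cannot change this distance. Limma called 0 to 15 ribosomal protein genes without 1 library, against 22. A single library stays open for the rise of acid resistance genes in the mutant itself, whose camera adjusted p of 0.0493 went up to 0.275 without a library, with the direction kept. Replicates within mutant groups correlated at 0.916 or more and libraries across them at 0.903 or less, but WT and ΔEF4+tet replicate 1 at 0.922. An exchanged treatment label of single mutant libraries was not favoured but stays open. Exchange of both pairs could not be told from the data. As labelled, maltose genes fell in both strains, whose responses correlated at 0.0994 or more over 19 settings, but the true relation is unknown. A different growth stage at harvest stays open beside an effect of EF4 on the response to the drug: the sigma S genes had a median interaction 4.70 above that of all genes, and the table holds no growth measure that could tell these apart.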

How the results depend on the processing

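Of the 492 gene results named by the rule, 334 kept their side of the threshold under all settings that keep all 8 libraries, and 234 under all settings. Reversals numbered 0, where a change of sign counted only for a gene called in the main fit or under the setting. For genes called in neither, the direction was not checked. Beside the settings given below, the counts of genes called stayed within 1.5 times. With each library left out in turn, the count of genes called ranged from 100 to 498 for tetracycline in the wild type (511 with all libraries), 22 to 222 for tetracycline in the mutant (221), 0 to 49 for the mutant without (57) and 300 to 875 with tetracycline (868), and 32 to 236 for the interaction (323). Beside the 0, limma gave 545 genes at an unadjusted p under 0.05. The correlation of the responses of the strains ranged from 0.0994 to 0.166 and that of the mutation effects from 0.109 to 0.32, and the camera calls from 66 to 77. Leaving out a library removes samples and residual degrees of freedom, and the lone library of its group is assumed to vary like the other groups.

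With only the groups compared in the fit, fewer samples set the error, and the counts were 336 and 107 for tetracycline in wild type and mutant and 24 for the mutant without the drug. A pseudocount of 0.1 gave 4 for the mutant without the drug, and median centring, added after the data were seen, 92; the cause was not tested. With replicate number as block, counts were 907 and 631 for tetracycline in wild type and mutant, 141 and 1288 for the mutant without and with it, and 683 for the interaction. Deviations of equally numbered replicates from group means correlated across genes at 0.16 to 0.448 over group pairs, but the labels name no pairs. The block lost the acid resistance call for tetracycline in the mutant and kept the other 72 camera calls. Genes called in opposite directions by tetracycline in the strains numbered 130 with the block and 15 with only the groups compared, against 43. With the block, genes higher in the mutant both without and with the drug numbered 27 against 15.3 if the calls were independent, and 5 were called in opposite directions; quantile normalization gave 2, median centring and the fits without WT replicate 1 or WT+tet replicate 2 gave 1 each, and the other settings 0.

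With an estimated correlation, camera called 0 of 185 list tests (18 at an unadjusted p under 0.05), where the preset correlation gave 73 and fry 55 (fry kept 38 of the 73); the cause was not tested. After quantile normalization and median centring, added for lists after the data were seen, 64 and 71 of the 73 calls were kept, and the others are named beside their results. Of the 73, 44 were kept without each library and 2 reversed. Anaerobic respiration in the mutant without the drug turned down without WT replicate 1, its adjusted p ranging from 4.17e-12 to 0.304 over the libraries left out. The TCA cycle there turned down without WT replicate 2, its adjusted p ranging from 4.47e-05 to 0.954; the cause was not tested. Tests and size factors that need deposited counts were not run because the table holds RPKM, and removal of ribosomal and transfer RNA was not run because the table has 0 such entries. For genes listed at 0, a change is limited by depth and by the pseudocount.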

Other observations

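Some further genes that the rule named stood out in 1 comparison each. In the wild type, tetracycline raised a methyltransferase gene and an acetyltransferase gene that follow each other in the table, gene4763 (4.82 ± 0.55, adjusted p = 0.0024) and gene4764 (4.72 ± 0.67, adjusted p = 0.00633), the antitoxin gene yafW (5.17 ± 0.84, adjusted p = 0.0101; 0.0801 without WT+tet replicate 2) and a transposase gene, gene1096 (5.398 ± 0.48, adjusted p = 0.000801). The tryptophanase leader peptide gene tnaC fell with tnaA (-7.32 ± 1.17, adjusted p = 0.00967; 0.0613 without WT replicate 2). In the mutant, the drug raised the outer membrane stress gene bhsA (5.19 ± 0.94, adjusted p = 0.0292; 0.191 without ΔEF4 replicate 2).

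With the drug, 4 of 20 DNA damage genes were called higher in the mutant than in the wild type and 0 lower, among them recN (1.87 ± 0.43), sulA (2.30 ± 0.60) and uvrA (1.37 ± 0.35) but not recA. The list as a whole had a median of 0.08, -0.07 after quantile normalization, and no camera call (adjusted p = 0.499). The anaerobic glycerol genes glpC (5.47 ± 0.89) and glpB (5.22 ± 0.91) lay higher there and the sialic acid lyase gene nanA (-4.79 ± 0.67) lower. Calls lost without 1 library were those of recN (0.122 without WT+tet replicate 2), sulA (0.171 without WT+tet replicate 2), uvrA (0.193 without WT+tet replicate 2) and glpB (0.0605 without WT+tet replicate 2).

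The tests of the fdo genes were chosen after the result was seen. In the mutant, fdoH and fdoI stayed at 1.33% to 7.02% of the wild-type mean. An equal change of the whole operon was excluded, since the entry taken as fdoG fell by at least 1.79 less on the log2 scale than either in both comparisons, while fdhE, downstream, stood at 68.7% and 27.8%. A DNA lesion in the mutant strain could not be told from lower transcription, since the table gives no positions within genes: 6 genes among those at 10 RPKM or more in each wild-type library, lepA, fdoH, fdoI, borD, gene619 and plaP, had all 4 mutant libraries under 25% of the lowest wild-type library. Whether any of them follows from the loss of EF4 was not tested, as the series holds 1 mutant strain.

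The test of the shift of all genes was also chosen after the result was seen. In the mutant the median log2 fold change of all genes with tetracycline was 0.50, against 0.02 in the wild type. A few abundant genes taking a changing share of the reads was excluded as the whole cause of the shift in the mutant. With each library scaled by its total without the 50 most abundant genes, the median of the others was 0.43. In the wild type the same scaling took the median of the others from 0.02 to 0.19, so the strains lay closer together. Abundant genes therefore stay open as a cause of part of the difference between the strains. Those 50 took 28.5% to 30.6% of the reads without and 22.5% to 25.4% with the drug in the mutant. In the wild type they took 26.5% to 30.4% without and 33.6% to 40.7% with the drug. No biological explanation was tested.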
